A study of Homo sapiens with 2 samples.

How the data were processed

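Exosomes from the medium of H1299 cells, an established p53-null human non-small cell lung cancer line, were profiled on a human miRNA microarray after 0 Gy or 10 Gy of ionizing radiation. Per the labels, the cells grew in RPMI-1640 medium with 10% serum, and the irradiated cells were exposed on a linear accelerator at 400 cGy per minute and a source-to-skin distance of 100 cm. The labels name a mirVana kit for RNA extraction. They describe Cy3 labelling from 0.2 µg RNA by a linear amplification chemistry for cRNA, which is an mRNA labelling method, so the labelling of the small RNA is not settled by the sources used here. How the exosomes were isolated, how long after irradiation and whether the serum was depleted of vesicles are not given in the sources used here. There was 1 array per dose, 2 arrays in all, and both lay on 1 slide read in 1 scan, per the file headers, so slide and scan do not separate the doses.

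The deposited scanner files hold spot intensity values on a linear scale from Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. Per the file headers, the processed intensity had been background-subtracted and spatially detrended within each array, with no scaling between arrays. The deposited value table holds log2 values with 1 row per miRNA. Its scale and column order could be matched to the scanner totals. Its normalization steps are not stated, and both of its columns have a median of -3.32, the floor, which is log2 of the scanner's minimum total of 0.1. It was used only as an alternative.

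Each array had 53144 spots, of which 50980 belonged to 5893 probes for 2549 human miRNAs. Control spots and spots marked as outliers (1528 on the 0 Gy array and 1465 on the 10 Gy array) were left out, and no spot was saturated. The processed signal of the remaining spots of a probe was averaged. A probe was called detected when at least a share of 0.5 of its spots was marked well above background, and a miRNA when any of its probes was. Signals were divided by the array's 75th percentile over the 330 probes detected on both arrays, then put on a log2 scale. Each miRNA took its probe with the highest mean scaled value. Among 127 miRNAs with at least 2 probes detected on both arrays, the median gap between probe differences was 0.13 log2 units, and 1 miRNA, miR-4505, had probes of opposite sign more than 1 unit apart. For miR-4788, the probe chosen was not detected on the 10 Gy array, although another of its probes was. The array files give miRNA names and capture sequences but no genomic coordinates, and the gene table at hand is of another build than the array's design file (hg19), so no positions are given.

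Differences are 10 Gy minus 0 Gy on the log2 scale. With 1 array per dose there is no residual degree of freedom, so no p-value was computed, and miRNAs were described by a size rule of 2-fold. The spot-to-spot SD combines the log2 SDs over the spots of both arrays, mostly 10 spots per probe. It is a technical spread within arrays and leaves out culture, isolation and labelling. The number of arrays limits the precision. For a miRNA detected on 1 array only, the fold is a lower bound. It sets the bright signal against the higher of the miRNA's own signal on the other array and that array's lowest detected probe signal, 14.9 at 0 Gy and 13.9 at 10 Gy before scaling, and no fold is given where it is below 1. A miRNA list with at least 3 members detected on both arrays was placed by its median's percentile among 10000 random lists of equal size matched on mean level in 5 bins.

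Lists, settings and the naming rule were fixed before the data were examined. Named are the 10 largest and 10 smallest differences with spot ranges apart, and the 5 largest bounds on each side. The 5 brightest miRNAs per array, up to 4 detected members of each list, and miR-21-5p, miR-34a-5p and miR-210-3p are named as well. Names follow the array design without its species prefix. Other names are given as chosen after their values were seen. Alternatives covered scaling (75th percentile over all probes, median, quantile, none), normexp background correction with an offset of 50, total gene signal, the mean of probes, the value table, 3 other detection rules, outlier spots and a size rule of 1.5-fold. Scaling on spike-in controls and a restriction to miRNAs well above the 10 Gy floor were added after the data were seen. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, normexp with limma 3.58.1 in R 4.3.3, and plots with matplotlib 3.10.9.

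The calculation was tested on simulated spots made from the 0 Gy array, with the second array made dimmer. Of 311 miRNAs, 200 were changed, by 1.5 or 2 log2 units up or down. Of 100 raised miRNAs, 96 stayed measurable on both arrays and 95 met the 2-fold rule. Of 100 lowered miRNAs, 24 stayed measurable on both arrays and all 24 met the rule. Requiring detection on a dimmer array thus removed most miRNAs lowered by these sizes from the simulated comparison. The median error of the difference was -0.28 log2 units. Unchanged miRNAs had a median difference of -0.27, so the error was mostly a common offset.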

Results

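The series asked how the miRNA content of exosomes released by H1299 cells differs after 10 Gy of ionizing radiation. Exosomes are small membrane vesicles that cells release into their medium, and miRNAs are short RNAs that repress messenger RNAs. The design has 1 array of exosomal RNA from unirradiated cells (0 Gy) and 1 array from irradiated cells (10 Gy), so no difference below has a replicate check and none was tested. All errors are spot-to-spot SDs within the arrays. The 10 Gy array was the dimmer one. Its scanner total at the 99th percentile was 75.8, against 161.9 at 0 Gy, and 6.49% of its miRNA spots were well above background, against 10.8%. Negative control spots averaged 2.31 on the 10 Gy array and 1.92 on the 0 Gy array (SD over 1000 spots each, 2.89 and 2.69).

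Exosomes from unirradiated cells gave signal for more miRNAs than those from irradiated cells. Of 2549 human miRNAs on the array, 311 (12.2%) were detected at 0 Gy and 199 (7.81%) at 10 Gy, with 194 detected on both. The signal was held by few miRNAs. miR-6087 was the brightest on both arrays, at 32481 units before scaling at 0 Gy and 13303 at 10 Gy. It made up 26.3% of the summed signal of detected miRNAs at 0 Gy and 23.7% at 10 Gy, and the 5 brightest together made up 50.02% and 54.9%. The other bright miRNAs at 0 Gy were miR-8069, miR-7975, miR-4459 and miR-7977, and those at 10 Gy were miR-8069, miR-6089, miR-4459 and miR-4505. Scaled levels of the 194 shared miRNAs had a Spearman rho of 0.84 between the arrays, computed across miRNAs, which are not independent replicates.

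Before scaling, 174 of the 194 shared miRNAs were dimmer at 10 Gy and 20 were brighter, with a median 10 Gy to 0 Gy ratio of 0.478. The scaling raised the 10 Gy signals by 2.68-fold relative to those at 0 Gy. After it, the median difference was 0.36 log2 units and its quartiles were -0.25 and 1.05. The median spot-to-spot SD of a difference was 0.18, and the highest was 0.48.

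After scaling, 53 of the 194 shared miRNAs were at least 2-fold higher in exosomes of irradiated cells. The largest difference was that of miR-6803-5p, at 2.61 ± 0.09 log2 units (spot SD, 10 spots per array). Its signal before scaling was 368 at 0 Gy and 839 at 10 Gy. It was followed by miR-6739-5p at 2.33 ± 0.26, miR-4507 at 2.19 ± 0.07 and miR-6510-5p at 1.998 ± 0.098. miR-574-3p stood at 1.78 ± 0.29, miR-7110-5p at 1.78 ± 0.08, miR-125b-5p, a member of the miR-125 family, at 1.74 ± 0.42, and miR-8485 at 1.71 ± 0.25, which turned to -0.036 with total gene signal. miR-4505 (1.67 ± 0.03) and miR-1587 (1.66 ± 0.07) completed the 10 largest. Their probes share short sequences, which was seen after the ranking. CCAGCCC is held by the probes of miR-6803-5p, miR-4507, miR-4505 and miR-1587. TCTCT is held by those of miR-6739-5p, miR-6510-5p and miR-7110-5p. The 10 may therefore not be separate miRNA differences, which was not tested. Of these 10, miR-6739-5p, miR-574-3p, miR-125b-5p and miR-8485 were dim, with 20.7 to 31.7 units at 0 Gy. Under this scaling a miRNA as dim as these can be detected at 10 Gy only with a difference above 0, as was so for 23 of the 53. Without scaling, where this limit lies below 0, the 4 were still higher, at 0.91, 0.36, 0.32 and 0.29. Relative to the median of all shared miRNAs, which no common scaling factor changes, miR-6803-5p lay 2.25 log2 units higher and miR-1587 lay 1.31 higher. The 2 probes of miR-4505 disagreed, with a difference of 1.67 for the brighter and -0.03 for the dimmer. The dimmer one had 42.8 units at 0 Gy and 15.6 at 10 Gy. The other probe of miR-1587 also went the other way (-0.43 ± 0.47). It had 17.3 units at 0 Gy and 4.81 at 10 Gy, where it was not detected.

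**Figure D1:**
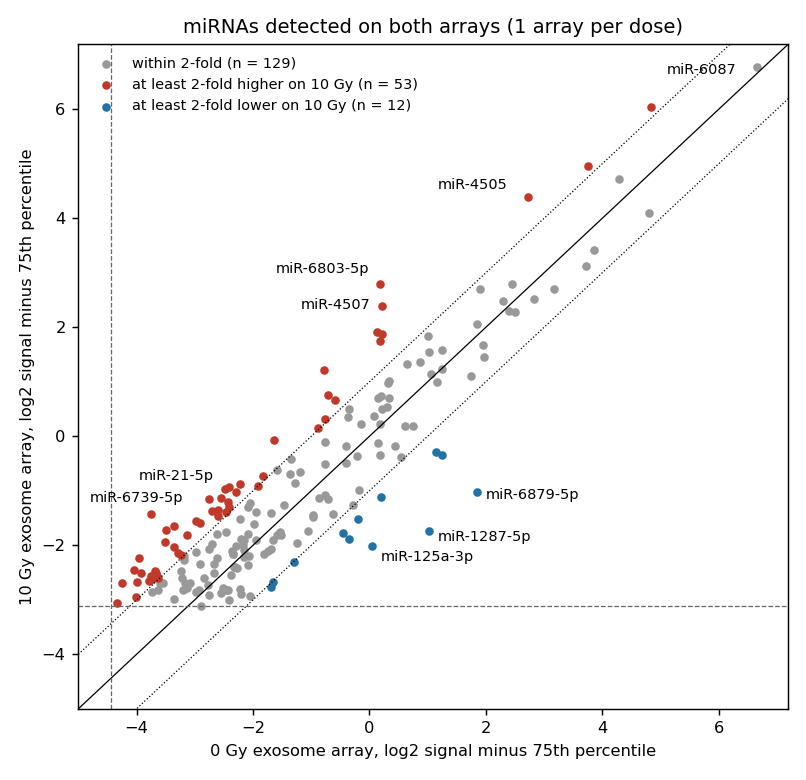
Scaled log2 signal of the 194 miRNAs detected on both arrays, 0 Gy on the x axis and 10 Gy on the y axis, each relative to the array's 75th percentile. Solid and dotted lines mark equal level and 2-fold, dashed lines mark each array's lowest detected probe signal, and the 53 higher miRNAs lie above the upper dotted line and the 12 lower ones below the lower dotted line. The split between the sides depends on the scaling, as without scaling it is 1 to 105.

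Fewer shared miRNAs, 12 of 194, were at least 2-fold lower in exosomes of irradiated cells, but the 3 largest of these differences came from bright probes. miR-6879-5p differed by -2.87 ± 0.12 log2 units, with 1165 units at 0 Gy and 59.5 at 10 Gy before scaling. miR-1287-5p differed by -2.75 ± 0.17, with 657 and 36.4 units. miR-125a-3p, the 3′ arm of the miR-125a precursor, differed by -2.06 ± 0.15, with 332 and 29.8 units. miR-4497 (-1.59 ± 0.07), miR-575 (-1.53 ± 0.19) and miR-6126 (-1.43 ± 0.12) came next. miR-6763-5p stood at -1.32 ± 0.07, miR-4485-5p at -1.32 ± 0.18, miR-8063 at -1.31 ± 0.13 and miR-6893-5p at -1.08 ± 0.27. With normexp background correction these 4 were at -0.82, -0.65, -0.55 and 0.0033, and miR-4485-5p was at -0.91 with the mean of probes. Normexp here adds 50 units to every spot, above the 10 Gy detection floor of 13.9, which compresses the ratios of dim signals. The remaining members of the 12 were miR-1237-3p and miR-671-5p, chosen after their values were seen. All 12 were also at least 2-fold lower with each of the other scalings tried, but 5 of them with normexp, 10 with the mean of probes and 11 in the value table.

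No test applies to the 53 and the 12, and their split depends on the scaling. It became 31 higher and 17 lower with the median in place of the 75th percentile, 38 and 16 with quantile normalization, 4 and 54 with the 75th percentile over all probes, and 1 and 105 without scaling. Scaling on spike-in controls, chosen after the data were seen, gave 0 higher and 167 lower for labelling controls and 0 and 115 for hybridization controls, and with labelling controls 8 of the 10 largest differences turned negative.

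**Figure D2:**
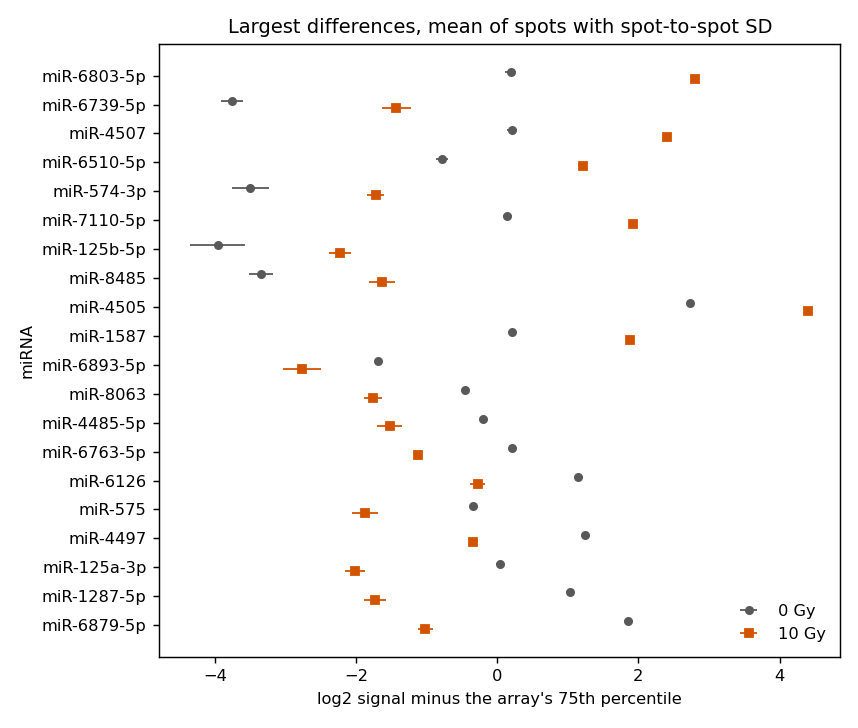
The 10 largest and 10 smallest differences, with scaled log2 signal on the x axis and 1 miRNA per line. Circles are the 0 Gy array and squares the 10 Gy array, each the mean over the spots of 1 probe with the spot-to-spot SD as bar, and the widest separation is that of miR-6879-5p at -2.87 log2 units.

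Detection on 1 array only was almost all on the unirradiated side. There were 117 miRNAs detected at 0 Gy only and 5 at 10 Gy only. Because the 10 Gy array was dimmer, 24 of the 117 had a bound above 1-fold and 4 had a bound of at least 2-fold. These were miR-1249-5p, at least 2.54-fold lower at 10 Gy, miR-1233-5p (2.22-fold), miR-4465 (2.13-fold) and miR-4257 (2.05-fold), followed by miR-4745-5p at 1.49-fold. Of the 5 detected at 10 Gy only, miR-6809-5p was at least 3.51-fold higher after scaling and miR-425-3p at least 3.13-fold. miR-4649-3p, miR-4313 and miR-6756-3p were at least 2.87-fold, 2.71-fold and 2.70-fold higher after scaling. Their signals before scaling were 15.1 to 19.6 units at 10 Gy, close to the detection floor of 13.9, and 13.4 to 15.4 at 0 Gy. Most of each fold thus comes from the 2.68-fold scaling. Without scaling the log2 bounds were 0.39, 0.23, 0.10, 0.018 and 0.013, in the order named. With labelling spike-in scaling all 5 of these bounds fell below 1-fold, and with hybridization spike-ins 4 did.

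Most miRNA families named in advance were near or below detection. Outside the list of GC-rich miRNAs, 15 of 136 listed miRNAs on the array were detected at 0 Gy and 10 at 10 Gy. No member was detected on either array for the miR-15/16 family (7 on the array), the p53-regulated list (11), the miR-30 family (5), the miR-200 and epithelial list (7) or the chromosome 19 cluster (19). Of 9 let-7 family members, tumour suppressors that repress RAS messenger RNAs, let-7b-5p was detected, at 0 Gy only (31.2 units). miR-34a-5p, a direct p53 target, and miR-210-3p, which hypoxia induces, were not well above background on either array.

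Among miRNAs abundant in tumour cells, miR-21-5p had 60.3 units at 0 Gy and 52.3 at 10 Gy before scaling, a scaled difference of 1.22 ± 0.20 that turned to -0.21 without scaling. Of the same list of 10, miR-155-5p was detected at 0 Gy only, and the rest were not detected. Of 12 members of the miR-17/92 cluster and its paralogues on the array, miR-25-3p was detected, with a difference of 1.13 ± 0.34 (-0.29 without scaling). The miR-23/27/24 clusters gave miR-23a-3p at 1.16 ± 0.36 (-0.26 without scaling) and the miR-29 family miR-29a-3p at 0.89 ± 0.36, whose spot ranges overlapped and which was -0.53 without scaling. Of 15 miRNAs reported to act on DNA damage response transcripts, miR-100-5p was detected on both arrays at 0.83 ± 0.16 (-0.59 without scaling), and miR-155-5p at 0 Gy only. miR-125b-5p and miR-100-5p were the detected members of the 5 in the miR-99/100 and miR-125 clusters. Of these 6 miRNAs, miR-125b-5p, miR-25-3p, miR-23a-3p and miR-29a-3p had 20.7 to 26.8 units at 0 Gy. At that level and with this scaling, detection at 10 Gy alone sets a difference of at least 0.48, and without scaling only miR-125b-5p stayed higher (0.32). miR-100-5p, with 78.3 units at 0 Gy and 52.0 at 10 Gy before scaling, and miR-21-5p are not limited in this way, and lay 0.47 and 0.86 above the median of all shared miRNAs.

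The list of miRNAs reported as sorted into exosomes had too few members detected on both arrays, 2 of 6, to be placed as a list. These were miR-575 and miR-125a-3p, both at least 2-fold lower at 10 Gy with every scaling tried, although with normexp background correction miR-575 was at -0.67 and miR-125a-3p at -1.04. miR-601 and miR-887-3p were detected at 0 Gy only, with a bound of 1.01-fold for miR-887-3p and none for miR-601, and the other members were not detected. In the chromosome 14 cluster, 3 of 28 members were detected, of which miR-370-3p at 0 Gy only. Under this scaling, miR-494-3p (0.07 ± 0.09) and miR-134-5p (-0.16 ± 0.28) were within their spot spread of no difference. They were at -1.35 and -1.58 without scaling, and at -0.09 and 0.47 with normexp.

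GC-rich miRNAs that are often bright on arrays of this kind were the only well-covered list, with 24 of 24 on the array detected at 0 Gy and 22 at 10 Gy. Their median difference was 0.44 log2 units, at percentile 83.7 of the matched random lists, whose 5th and 95th percentiles were -0.08 and 0.53. With the 75th percentile over all probes the list median was -0.38, and without scaling it was -0.98. At least 2-fold higher were 3 of the 22, namely miR-8069 (1.20 ± 0.04), miR-6089 (1.20 ± 0.03), both -0.22 without scaling, and miR-6869-5p (1.56 ± 0.06), the last chosen after its value was seen and with a gap of 0.91 between its probes. None was at least 2-fold lower. With the probe chosen, miR-6087 (0.13 ± 0.08) and miR-3960 (-0.09 ± 0.05) differed little under this scaling. They stood at -0.69 and -0.91 with the 75th percentile over all probes and at -1.29 and -1.51 without scaling. The probes of miR-6087 had a gap of 0.715. With the mean of probes miR-6087 was at -0.22 and miR-3960 at 0.0026. Of the remaining bright miRNAs, miR-4459 differed by 0.44 ± 0.05, miR-7975 by -0.71 ± 0.04 and miR-7977 by -0.44 ± 0.04. Without scaling these were -0.98, -2.13 and -1.86, and miR-4459 was also negative with the 75th percentile over all probes (-0.38), in the value table (-0.58) and with labelling and hybridization spike-ins (-1.87 and -1.20).

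Markers of other cells were nearly all undetected, which does not show that they were absent. Of all miRNAs on the array, 12.2% were detected at 0 Gy and 7.81% at 10 Gy. Of the 136 miRNAs in the family and pathway lists outside the GC-rich one, 15 and 10 were. Of 28 miRNAs typical of red blood cells and serum, liver, blood leukocytes, endothelium, mesenchyme, muscle and neurons, 1 was detected at 0 Gy and 0 at 10 Gy. The one detected was miR-206, a skeletal muscle miRNA, at 24.7 units at 0 Gy, which was not well above background at 10 Gy.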

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

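All tests in this part were chosen after the data were seen. The spike-in controls, sequences added in fixed amounts and named in the scanner's quality metrics, were outside the comparisons and were brighter on the 10 Gy array than on the 0 Gy array, while the miRNAs were dimmer. The labelling controls dmr_285 and dmr_31a had 10 Gy to 0 Gy ratios of 1.79 and 1.95, and the hybridization controls dmr_6 and dmr_3 had ratios of 1.18 and 1.16. Weaker hybridization or scanning of the whole 10 Gy array would have lowered these controls too, and the lowest of the 4 ratios, 1.16, argues against it. These ratios are also the observation that raised the question, so they are not a separate test of it. The median miRNA ratio before scaling was 0.478, so less exosomal small RNA in the 10 Gy labelling reaction is a candidate explanation. The labels give the same RNA input, 0.2 µg, for both arrays. The signals can therefore show a share of the labelled RNA, but not the amount of miRNA released per cell. An effect of radiation on that share, a difference in the RNA taken up into the reaction and a difference in its purity stay open with 1 array per dose. None of them was tested.

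Control sequences of other kinds, whose roles the files do not state, were dimmer on the 10 Gy array, with ratios from 0.216 for hur_6 to 0.655 for hur_4.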

How the results depend on the processing

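The spike-in scalings and the level restriction were chosen after the data were seen. Signal over background on the dimmer 10 Gy array limits all results, since lowered miRNAs drop out of the comparison there. The counts of miRNAs at least 2-fold higher and lower, 53 and 12, became 4 and 54 with the 75th percentile over all probes, 31 and 17 with the median, 1 and 105 without scaling, and 0 and 167 or 0 and 115 with labelling or hybridization spike-ins, as a common shift makes them. That shift of the median was -0.82, -0.26, -1.42, -2.32 and -1.65 log2 units, and -0.18 for quantile normalization. The counts were 31 and 6 with normexp, whose offset of 50 units added to every spot compresses the ratios of dim signals. How much of that change the offset makes was not tested. With total gene signal they were 29 and 21 (the cause was not tested). They were 33 and 12 when all spots had to be above background (160 compared, 45 and 10 of them before the scaling reference also moved, by -0.17 for each). They were 28 and 10 at least 2-fold above the 10 Gy floor (120 compared), and 80 and 25 with the 1.5-fold rule. Within 1.5 times of 53 and 12 were quantile normalization (38 and 16), the mean of probes (49 and 11), the value table (44 and 17), the scanner's gene call (79 and 18) and no detection filter (61 and 16, with signals below an array's lowest detected one set to it and counted only where the other array was brighter). Detected miRNAs ranged from 264 to 426 at 0 Gy and from 162 to 275 at 10 Gy. Those at 0 Gy only ranged from 104 to 155, and those at 10 Gy only were 5, or 2 when all spots had to be above background and 4 with the gene call. The GC-rich list median of 0.44 was -0.38 with the 75th percentile over all probes, 0.18 with the median, 0.14 with quantile normalization, -0.98 without scaling, -1.88 and -1.21 with labelling and hybridization spike-ins, 0.27 when all spots had to be above background, by that same -0.17, and, with the cause not tested, 0.25 with normexp, 0.10 with total gene signal and 0.16 with the value table. Of the 10 largest differences, 8 turned negative with labelling spike-ins, namely miR-4507 (-0.13), miR-6510-5p (-0.32), miR-574-3p (-0.54), miR-7110-5p (-0.54), miR-125b-5p (-0.58), miR-8485 (-0.60), miR-4505 (-0.65) and miR-1587 (-0.66). Without scaling, and with labelling and hybridization spike-ins, miR-8069 was -0.22, -1.12 and -0.45, miR-6089 -0.22, -1.12 and -0.45, miR-25-3p -0.29, -1.19 and -0.52, miR-23a-3p -0.26, -1.16 and -0.49, and miR-21-5p -0.21, -1.10 and -0.43. The cause was not tested for miR-8069 at -0.24 in the value table and miR-8485 at -0.036 with total gene signal. For miR-6893-5p, at 0.0033 with normexp, the signal of 17.7 units at 10 Gy lies below the offset of 50. The bounds of miRNAs detected at 10 Gy only were lost for 5 with labelling and 4 with hybridization spike-ins. No paired analysis was possible because each dose had 1 array.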

Other observations

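The tests in this part were chosen after the data were seen. Both arms of a precursor were detected on both arrays for 8 precursors. In 5 of them the differences of the arms had opposite signs after scaling, with that of the 3′ arm the positive one. Without scaling 2 of these 5, miR-197 and miR-574, kept opposite signs. For miR-197 the 5′ arm differed by -0.92 ± 0.11 log2 units (spot SD) and the 3′ arm by 1.56 ± 0.36. The arms of miR-4485 stood at -1.32 ± 0.18 and 1.099 ± 0.229, those of miR-574 at -0.23 ± 0.08 and 1.78 ± 0.29, and those of miR-3162 at -0.56 ± 0.07 and 1.09 ± 0.27. miR-1228 gave -0.34 ± 0.21 and 0.88 ± 0.48. The gap between the arms, which no common scaling factor changes, was 2.48 for miR-197 and 1.21 for miR-1228. The 3′ arms of all 5 were dim, at 16.9 to 61.0 units at 0 Gy before scaling. For 4 of them, all but that of miR-4485, a signal at the 10 Gy detection floor of 13.9 already gives a scaled difference above 0, from 0.39 for miR-574 to 1.14 for miR-197. The count of 5 therefore depends on the scaling and the detection rule together.

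The probes of detected miRNAs were rich in G and C. The median GC share of the probe was 71.0% for the 194 miRNAs detected on both arrays and 50% for miRNAs detected on neither. Across the 194, GC share and difference had a Spearman rho of 0.12, and mean level and difference had one of -0.24, across miRNAs that are not independent replicates.

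After scaling, the miRNAs whose probe held the sequence CCAGCCC lay high at 10 Gy. This sequence of 7 bases had the highest median difference, 1.66, of 18 such sequences found in at least 5 of the 194 miRNAs. Its 7 members were miR-6803-5p, miR-4507, miR-4505, miR-1587, miR-6779-5p, miR-937-5p and miR-671-5p. Before scaling, 4 of the 7 were brighter at 10 Gy, and miR-6779-5p, miR-937-5p and miR-671-5p were dimmer. When differences were shuffled within 5 level bins, 0.91% of 10000 shuffles gave any sequence as high a median, which argues against chance among these sequences, although other lengths were also searched (1.16% for 6 bases, and 0.66% for 5 bases with another sequence, TCTCT, leading). The probes of miR-4505 with and without the last base of the sequence, TCCGTCCCAGCCC and TCCGTCCCAGCC, differed by 1.67 ± 0.03 and -0.03 ± 0.22. The gap was 1.70, where the largest other gap of 127 miRNAs was 0.91, so these 2 probes did not change alike. The probe without the base was far dimmer, at 42.8 units at 0 Gy and 15.6 at 10 Gy, against 2144 and 2545. It was detected on both arrays and fell towards the 10 Gy floor of 13.9 from well above it, so the floor does not account for the gap. Which of the 2 probes follows miR-4505 is not known, so the gap cannot decide whether miR-4505 itself changed. The probes of miR-1587 and miR-6779-5p without that base gave -0.43 ± 0.47 and -0.83 ± 1.01, and neither was detected at 10 Gy. A candidate explanation is 1 RNA, more abundant at 10 Gy relative to the shared miRNAs, that binds probes with this sequence. However, 2 of the 7 members, miR-671-5p (-1.01) and miR-937-5p (0.26), lay at or below the median of all miRNAs, so this explanation stays open.

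The submitters' value table gave values to miRNAs that the scanner did not detect. Both columns hold 426 values above the floor, as does the scanner output at 0 Gy, but at 10 Gy the scanner detected 275. The 151 others carry values from -1.90 to -0.59 in the 10 Gy column, which hardly followed their measured signal (Spearman rho 0.12, against 0.97 for the 275), consistent with an order set by normalization and not by signal. The 0 Gy column has 151 values in the same low range, and 43 of them belong to miRNAs that the scanner detected at 10 Gy, where the median table difference was 2.95 and the median scaled signal difference 1.27. miR-125b-5p, for example, stood at 3.39 in the table and at 1.74 from its spots. Over the 422 miRNAs above the floor in both columns, the table gave 83 at least 2-fold higher and 76 lower. The 44 higher and 17 lower given above for the value table cover only the 194 shared miRNAs. No biological explanation was tested.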
